A study of Mus musculus with 143 samples.

How the data were processed

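Polyadenylated RNA from the striatum of 143 mice was sequenced, 1 library per mouse, and each library was compared as a separate animal, as the labels give them. The authors counted reads per gene with RSEM against the GRCm38 mouse genome, and the deposited table holds RSEM expected counts, which need not be whole numbers. The version of RSEM, the aligner and the gene annotation are not given in the sources used here. A second deposited table, named for FPKM values, has columns that each have the same sum and was not used here.

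The table of expected counts had 41135 entries for 143 libraries. Of these, 41128 named a mouse gene, 6 named a construct and 1 named a mutant form of Htt. The last 7 entries held 5.91e-06% of all counts and were left out of library sizes and tests. Expected counts were rounded to whole numbers before any test, a step that 78.2% of the nonzero values did not need. Total counts per library ran from 12.55 M to 29.19 M with a median of 18.85 M, and the 10 most abundant genes held 7.2% to 11.1% of the counts. No 2 libraries were identical. The levels of Xist and of Ddx3y matched the labelled sex in 143 of 143 libraries. Gene symbols were available for 40254 of the gene identifiers, and gene positions came from GENCODE M21 on GRCm38.

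Groups were taken from the labels: 2 genotypes, 3 treatments and 3 strategies, 18 groups in all. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, fitted once per strategy over its 6 groups with sex as a term, since those animals were taken to have been collected together and to share an estimate of the spread. Genes were kept by filterByExpr with the groups, libraries were scaled by TMM, and dispersions were estimated robustly. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that strategy. Standard errors are the fold change divided by the square root of F. Those given after covariates were added are the fold change divided by the normal quantile of its p value. The contrasts were zQ175 against wild type without treatment, HTT-10150 against NTC in each genotype, NTC against untreated in each genotype, and the difference of the HTT-10150 effect between genotypes. Differences between strategies came from 1 fit over all 143 libraries with sex within strategy, and differences between sexes from a fit of group by sex. These 2 kinds of difference were planned for the genotype effect and for HTT-10150 in zQ175. They were also computed for HTT-10150 in wild type and then dropped after their results had been seen, because the plan did not name them. The count table does not separate the wild-type from the mutant allele of Htt, so Htt values cover both.

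Htt levels per library are TMM-scaled CPM, compared between groups with exact two-sided permutation tests on the log2 scale. With 8 animals against 8, the smallest p such a test can give is 0.000155. The genotype signature score of a library was the mean log2 CPM (prior count 2) of the genes called higher in untreated zQ175 minus that of the genes called lower, with Htt left out. The score was compared by exact permutation, and the share of the zQ175 to wild-type distance (both NTC) covered by HTT-10150 was given a 95% interval from 10000 bootstrap draws of animals within groups. The untreated animals that chose the signature genes took no part in that test.

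The lists of genes, 26 in all, were written before the data were examined, as were the groups, the tests, the rule for the genes named in the text and the alternatives, except those said below to have been chosen later. Of their 475 symbols, 438 had an identifier in the table. The lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, and with camera with an estimated correlation and fry as alternatives. Adjusted p values of lists cover the lists of 1 contrast. The genes named were Htt, the 8 with the largest fold change in each direction among those called with a mean log2 CPM over 1 and the same direction in both sexes, up to 4 members of each list that passed camera or had at least 2 called members, and Drd1, Drd2, Penk, Pdyn, Tac1, Adora2a, Pde10a, Ppp1r1b, Gfap and Aif1. A gene named outside this rule is said to be so. Some genes that the rule names are not reported here.

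Alternatives recomputed each count of called genes, Htt and each named gene: DESeq2 1.42.0, RLE size factors, no filter on low counts, only the groups compared, no sex term, the replicate number within sex as a block, the number in the library name as a block (not for the genotype effect), untreated animals as the control for HTT-10150, NTC animals for the genotype effect, and leaving out each replicate number in turn from all groups. Chosen after seeing the data were 2 sets of covariates and a set of libraries left out. The first set held each library's slopes of gene levels on log2 transcript length and on GC content, fitted together and each in units of its SD over genes. Length and GC content were those of the longest transcript of a gene in GENCODE M21, which need not be the one expressed. The second held each library's mean level of choroid plexus, cortical, thalamic and oligodendrocyte marker genes. The libraries left out stood apart by choroid plexus or cortical genes.

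The test was tried on simulated counts with the group means, depths and spread of these libraries, in which 50 genes at each of 4 sizes were changed together in the zQ175 HTT-10150 group. The changed genes were drawn above a floor of mean level, and counts were drawn for each gene independently and without a sex effect. The recovery below may therefore not hold for genes at low levels, for genes that vary together, or where few genes change. Between 60% and 70% of genes changed 1.2-fold were called, 82% to 92% of those changed 1.3-fold, and 98% to 100% of those changed 1.5-fold. Between 6 and 17 unchanged genes were called. A planted return of 25% of the genotype signature was measured as 25.0% to 25.7%. Figures were drawn with matplotlib 3.10.9.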

Results

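RNA was measured in the striatum of zQ175 knock-in mice, a model of Huntington's disease that carries an expanded CAG repeat in its own Htt gene, and of wild-type mice. The animals were untreated, or were given HTT-10150, a small interfering RNA against Htt, or NTC, a non-targeting small interfering RNA. The 3 strategies are named by ages in months. Animals of 2[4]6 were treated at 2 months and collected at 6, those of 6[4]10 were treated at 6 months and collected at 10, and those of 2+6[8]10 were treated at 2 and again at 6 months and collected at 10. Each of the 18 groups held 8 animals, 4 female and 4 male, except wild-type mice given HTT-10150 in 2+6[8]10, of which there were 7 (2 female and 5 male). Total counts per library ran from 12.55 M to 29.19 M, with a median of 18.85 M. Levels below are TMM-scaled CPM as mean ± SD over the animals of a group, and log2 fold changes carry ± SE. Intervals and floors on counts cover counting error only.

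The comparison of untreated zQ175 with untreated wild-type mice addressed what the knock-in allele changes in the striatum at 6 months (2[4]6) and at 10 months (the other strategies). Genes of medium spiny neurons, the projection neurons that form most of the striatum, were lower in zQ175 in all 3 strategies. Of the 33 measured members of their list, 31 fell and 0 rose in each strategy, with the same counts adjusted over the list alone. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), which encodes the enkephalin precursor, stood at 511 ± 26.5 in zQ175 against 1251 ± 137 in wild type in 2[4]6. Its log2 fold change was -1.29 ± 0.07 there, -1.20 ± 0.08 in 6[4]10 and -1.25 ± 0.05 in 2+6[8]10 (n = 8 per group, adjusted p = 7.1e-20, 4.1e-16 and 1.1e-26). Ryr1, a calcium release channel, fell by 1.97, 2.68 and 2.55 on the log2 scale in 2[4]6, 6[4]10 and 2+6[8]10, and Scn4b, a sodium channel subunit, by 1.56, 1.67 and 1.67. The phosphodiesterase gene Pde10a fell by 1.06, 1.05 and 1.04, Arpp21 by 0.98, 0.91 and 0.98, and Ppp1r1b, which encodes DARPP-32, by 0.91, 0.69 and 0.81. The list passed camera in each strategy, and also with an estimated correlation (adjusted p = 0.015, 0.048 and 0.0054). Tac1, which encodes the substance P precursor, did not pass the test, with log2 fold changes of 0.15 ± 0.08, 0.13 ± 0.07 and -0.04 ± 0.06.

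Markers of the indirect pathway, the medium spiny neurons that carry the D2 dopamine receptor, fell together. Of 9 measured, 7, 7 and 6 fell in 2[4]6, 6[4]10 and 2+6[8]10 and 0 rose, and 7, 7 and 8 fell adjusted over the list alone. The adenosine receptor gene Adora2a fell by 1.003, 1.001 and 1.05 on the log2 scale and Drd2 by 0.79, 0.63 and 0.74. This list also passed camera with an estimated correlation (adjusted p = 0.015, 0.027 and 0.0053). Markers of the direct pathway, the neurons that carry the D1 receptor, moved both ways: of 10, 5, 3 and 5 fell and 2, 3 and 1 rose, with the same counts adjusted over the list alone. Drd1 fell by 0.74, 0.77 and 0.84, the muscarinic receptor gene Chrm4 by 0.92, 0.83 and 0.83, and Pdyn, the dynorphin precursor, by 0.37, 0.43 and 0.51, while Eya1 rose by 0.39, 0.35 and 0.35. The direct pathway list passed camera in 2+6[8]10 (adjusted p = 0.018), but not with an estimated correlation (adjusted p = 0.23), and did not pass in 2[4]6 or 6[4]10 (adjusted p = 0.25 and 0.30). Striatal interneuron markers fell in 6, 7 and 8 of 14 cases and rose in 0, and 7, 7 and 12 fell adjusted over the list alone. Among them were Kit (-0.29 ± 0.04, -0.29 ± 0.06 and -0.31 ± 0.05) and Chat, the enzyme of acetylcholine synthesis (-0.31 ± 0.09 in 6[4]10). With an estimated correlation, the interneuron list passed in 2+6[8]10 (adjusted p = 0.023) and not in 2[4]6 or 6[4]10 (adjusted p = 0.12 and 0.069). Immediate early genes, which neuronal activity induces, fell in 14, 6 and 4 of 20 cases and rose in 0, and 14, 5 and 2 fell adjusted over the list alone. Homer1 fell by 0.71, 0.71 and 0.74, and Egr2 by 2.28 in 2[4]6 and 1.55 in 6[4]10. The immediate early list passed camera in 2[4]6 and 6[4]10, and in neither with an estimated correlation (adjusted p = 0.36 and 0.73).

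**Figure D1:**
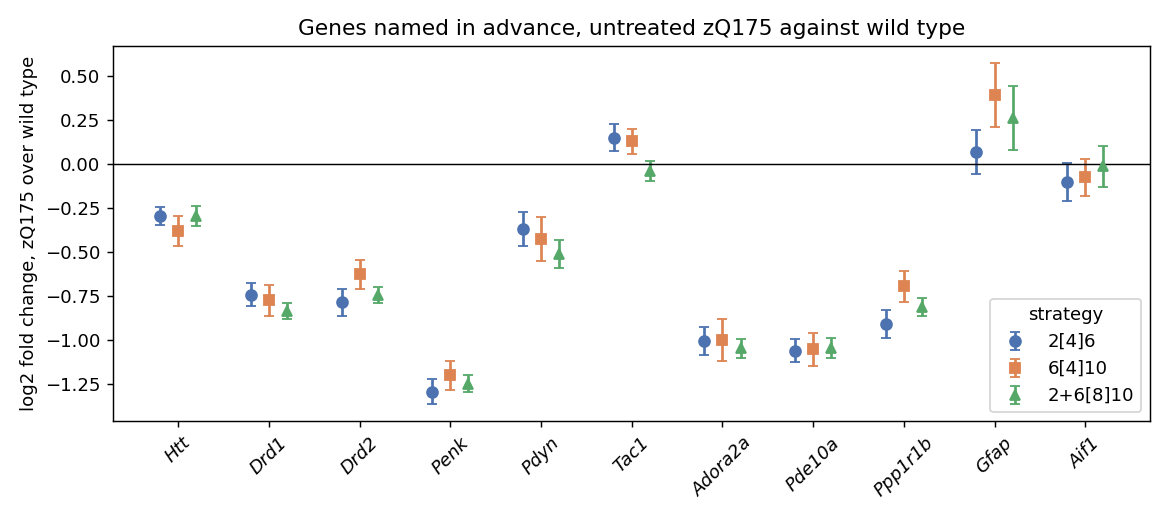
The log2 fold change of each gene named in advance (y axis) in untreated zQ175 against untreated wild-type mice, by gene (x axis) and strategy (marker and colour); bars are the standard error, with 8 animals per group. Htt, Drd1, Drd2, Penk, Pdyn, Adora2a, Pde10a and Ppp1r1b lie below 0 in the 3 strategies, and Tac1, Gfap and Aif1 did not pass the test.

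Developmental transcription factors and clustered protocadherins were higher in zQ175. Of the transcription factors measured, 8 of 10 rose in 2[4]6, and 10 of 13 in 6[4]10 and in 2+6[8]10, and 0 fell (8, 10 and 11 adjusted over the list alone). Hoxc4 (ENSMUSG00000075394, chromosome 15, 103018934 to 103036852) had 731 counts over the zQ175 group and 0 over the wild-type group in 6[4]10. Against a floor of 3 counts over the wild-type group this was at least 223-fold higher, and at least 225-fold in 2+6[8]10 (911 counts against 0). Onecut1 had a ratio of 50.3 (95% interval 24.2 to 126) in 2[4]6, 73.2 (39.6 to 153) in 6[4]10 and 365 (101 to 3020) in 2+6[8]10, where the wild-type group had 2 counts. Wt1 had ratios of 51.3 (26.8 to 112.8) in 2[4]6 and 43.2 (26.9 to 74.5) in 2+6[8]10. Sox11 rose by 0.74 ± 0.08 on the log2 scale in 2[4]6 and Pax6 by 0.49 ± 0.07 in 6[4]10. The list passed camera with an estimated correlation in the 3 strategies (adjusted p = 5.0e-04, 2.1e-04 and 4.7e-04). Members with almost no counts in untreated wild type, such as Hoxc4, passed the filter on low counts through other groups. Such members could only rise, so the counts and the camera result of this list follow in part from the filter. Of 23 clustered protocadherins, cell adhesion genes, 17, 17 and 16 rose and 2, 1 and 1 fell (18, 18 and 16 up adjusted over the list alone), with Pcdhb3 up by 0.82, 1.14 and 1.13 and Pcdhb9 by 0.58, 0.69 and 0.79. This list passed with an estimated correlation as well (adjusted p = 0.015, 0.016 and 0.042). Pcdhb genes are alike in sequence, so the split of reads between single members is uncertain.

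The largest single changes lay partly outside these lists. Sfmbt2 (ENSMUSG00000061186, chromosome 2, 10370510 to 10595253), a Polycomb group gene, was 3.94-fold, 4.50-fold and 4.39-fold higher in zQ175 in 2[4]6, 6[4]10 and 2+6[8]10, at 8.82 ± 1.32 against 2.24 ± 0.33 in the first. Kazald1 rose by 1.13 ± 0.13, 1.64 ± 0.12 and 1.76 ± 0.14 on the log2 scale. Abhd1, Tnnt2 and Slc45a3 rose by 1.38, 1.32 and 1.19 in 2[4]6. Nrn1, a neurite growth gene, rose by 2.51 ± 0.43 in 6[4]10 and 1.79 ± 0.30 in 2+6[8]10, and was at -0.27 ± 0.51 in 2[4]6. Gpx6 (ENSMUSG00000004341, chromosome 13, 21312125 to 21319624), a glutathione peroxidase gene, was 13.1-fold, 20.6-fold and 24.6-fold lower in zQ175. Mafa fell by 3.03, 3.25 and 2.67, Abhd11os by 2.59, 2.97 and 2.87, Sec14l3 by 2.15, 2.70 and 2.79, and Vwa7 by 2.72, 2.67 and 2.50. Alb and Rps12 were also among the largest decreases in 2+6[8]10, with wild-type levels that varied between animals by more than their mean (16.96 ± 31.01 and 8.11 ± 12.98).

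Markers of astrocytes, oligodendrocytes and vessels were lower in zQ175 for part of each list. Of 16 astrocyte markers, 11, 11 and 13 fell and 1 rose in each strategy (11, 12 and 13 down adjusted over the list alone). The bicarbonate transporter gene Slc4a4 fell by 0.34, 0.47 and 0.47 on the log2 scale, Slc1a2, the main glutamate transporter of astrocytes, by 0.46 in 6[4]10 and 0.44 in 2+6[8]10, and S100b rose by 0.41 in 2[4]6. The astrocyte list passed camera in the 3 strategies, and in 0 of them with an estimated correlation (adjusted p = 0.19, 0.34 and 0.13). Of 16 oligodendrocyte markers, 5, 6 and 8 fell, among them Mal (-0.33 ± 0.06, -0.42 ± 0.09 and -0.51 ± 0.09), and 1, 0 and 0 rose, with the same counts adjusted over the list alone. That list passed camera in 2+6[8]10 (adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.90). Of 15 endothelial and mural markers, 13, 11 and 7 fell and 0 rose (13, 13 and 7 adjusted over the list alone), with Pecam1 at -0.31 ± 0.06, -0.30 ± 0.05 and -0.21 ± 0.06. The vascular list passed camera in 2[4]6 and 6[4]10, and in neither with an estimated correlation (adjusted p = 0.25 and 0.11). Of 5 blood genes, 3, 5 and 0 fell and 5, 5 and 0 adjusted over the list alone, and the list passed camera in 6[4]10 (adjusted p = 0.012), but not with an estimated correlation (adjusted p = 0.50). At 10 months, genes of activated microglia moved apart from the rest of their list: Cst7 rose by 2.17 ± 0.39 in 6[4]10 and 1.96 ± 0.33 in 2+6[8]10, the receptor gene Clec7a by 1.22 ± 0.22 and 1.55 ± 0.26, and Itgax by 1.47 ± 0.26 and 1.63 ± 0.29. In all, 0 of 14, 6 of 16 and 4 of 15 members of that list rose and 3, 1 and 2 fell (0, 6 and 4 up and 2, 2 and 2 down adjusted over the list alone), and it did not pass camera (adjusted p = 0.49, 0.14 and 0.54). Gfap and Aif1, markers of astrocytes and microglia, did not pass the test in any strategy, with Gfap at 0.07 ± 0.12, 0.39 ± 0.18 and 0.26 ± 0.18.

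Other lists passed camera in 1 strategy or in all 3. Of 23 interferon response genes, 4 rose and 0 fell in 2+6[8]10 (2 up adjusted over the list alone), among them Irf7 (0.70 ± 0.16), and the list passed camera (adjusted p = 0.037) but not with an estimated correlation (adjusted p = 0.83). Its counts in 2[4]6 and 6[4]10 were 1 and 1 up and 4 and 1 down (0 and 1 up and 0 and 0 down adjusted over the list alone). Of the genes that were lower, Bst2, Ifitm3 and Rsad2 in 2[4]6 and Rsad2 in 6[4]10 changed sign with NTC animals for the genotype effect (0.245, 0.09, 0.26 and 0.22) and did not pass there. Of 29 respiratory chain genes, 15 rose and 1 fell in 6[4]10 (18 and 1 adjusted over the list alone), with Sdha at 0.11 ± 0.02 and Atp5b at 0.14 ± 0.03, and 2 rose and 2 fell in each of the other strategies. The respiratory chain list passed camera in 6[4]10 (adjusted p = 3.5e-04), but not with an estimated correlation (adjusted p = 0.73). In that comparison fold changes also fell with length across genes (rho -0.174, exact p of the slopes 0.048, adjusted p = 0.24), and the list was lower in zQ175 given NTC than in untreated zQ175 (median -0.08, 0 called, 3 down adjusted over the list alone). Between NTC and untreated zQ175 in 6[4]10, 0 of 26 lists passed with an estimated correlation. Of 12, 12 and 11 genes of mismatch repair and repeat instability, 4, 5 and 5 rose and 0 fell (4, 6 and 6 adjusted over the list alone), such as Msh6 (0.20 ± 0.05 in 2[4]6), Mlh3 (0.18 ± 0.04 in 6[4]10) and Lig1 (0.25 ± 0.07 in 2+6[8]10). This repair list passed camera in the 3 strategies, and with an estimated correlation in 2[4]6 (adjusted p = 0.034) and not in 6[4]10 or 2+6[8]10 (adjusted p = 0.27 and 0.061).

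Over all genes, the genotype test called 5122 of 15716 in 2[4]6 (2412 up and 2710 down), 5691 of 15757 in 6[4]10 (3018 and 2673) and 5483 of 15506 in 2+6[8]10 (2645 and 2838). In all 3 strategies, 1257 genes rose and 1559 fell, where independent calls would give 79.1 and 85.0. In some pair of strategies, 12 genes were called in opposite directions. The strategies also differ in collection time and cohort, so a difference between them, here or for HTT-10150, has no single cause. In the fit of all 143 libraries, the genotype effect differed between 6[4]10 and 2[4]6 for 136 genes, 68 in each direction. Ryr1 was lower by a further 0.72 ± 0.12 in 6[4]10, Papln by 0.89 ± 0.16, and the effects on Rasl10a and Nrn1 were higher by 0.89 ± 0.18 and 2.78 ± 0.60. Between 2+6[8]10 and 2[4]6 the genotype effect differed for 11 genes. Among them were Alb (-12.18 ± 1.56), Apoa1 (-5.21 ± 0.74), Apoa2 (-3.68 ± 0.75), Ryr1 (-0.57 ± 0.12), Irf8 (0.55 ± 0.11) and Alx4 (2.33 ± 0.48). The wild-type level of Alb in 2+6[8]10 varied between animals by more than its mean, as given above. Between 2+6[8]10 and 6[4]10 the genotype effect differed for Apoa1 and Apoa2 (-3.91 ± 0.78 and -3.94 ± 0.75). DESeq2 called 294, 27 and 2. No gene's genotype effect differed between females and males with edgeR in any strategy; 384, 1538 and 860 genes had an unadjusted p under 0.05, and DESeq2 called 0, 22 and 0.

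The level of Htt itself was compared between treatments in each genotype, to measure how far HTT-10150 lowered its target. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) was 19.7% lower with HTT-10150 than with NTC in zQ175 in 6[4]10 and 21.9% lower in 2+6[8]10, and it was 16.2%, 20.9% and 27.9% lower in wild type in 2[4]6, 6[4]10 and 2+6[8]10. In zQ175 in 2[4]6 it stood at 126.5 ± 9.4 with HTT-10150 and 127.1 ± 10.7 with NTC (exact permutation p = 0.92). The zQ175 levels were 105.1 ± 10.7 against 130.8 ± 10.7 in 6[4]10 (n = 8 each, exact permutation p = 4.7e-04) and 107.4 ± 11.97 against 137.5 ± 5.3 in 2+6[8]10 (exact p = 1.6e-04, the smallest possible). In wild type they were 127.9 ± 13.4 against 152.7 ± 4.4 (exact p = 1.6e-04), 124.3 ± 25.3 against 157.1 ± 8.1 (exact p = 4.7e-04) and 116.4 ± 16.03 (n = 7) against 161.5 ± 8.2 (exact p = 1.6e-04). Adjusted over these 6 comparisons, the exact p was 0.92 for zQ175 in 2[4]6 and between 3.1e-04 and 5.6e-04 for the others. Every treated animal was below the lowest NTC animal in wild type in 2[4]6 and in both genotypes in 2+6[8]10. Adjusted over all genes by edgeR, Htt passed in 2+6[8]10 in zQ175 (-0.36 ± 0.06, adjusted p = 3.5e-04) and wild type (-0.49 ± 0.06, adjusted p = 5.0e-06), and not in 2[4]6 (wild type -0.26 ± 0.05, adjusted p = 0.057) or 6[4]10 (-0.32 ± 0.08 and -0.34 ± 0.08, adjusted p = 0.60 and 0.82). With length and GC slopes as covariates, chosen after the result was seen, Htt in zQ175 in 2+6[8]10 was at -0.26 and did not pass (adjusted p = 0.10, 7.7e-07 to 0.10 over the alternatives). In the fit of all 143 libraries it passed in wild type in 6[4]10 as well (adjusted p = 0.018). In that fit it did not pass in zQ175 in 6[4]10 or in wild type in 2[4]6 (adjusted p = 0.13 and 0.66). Nor did the effect of HTT-10150 on Htt in zQ175 pass as different between strategies. Its adjusted p over all genes was 0.91 for 2+6[8]10 against 6[4]10, and 0.088 and 0.60 for 2+6[8]10 and 6[4]10 against 2[4]6. The effect differed between the genotypes in 2[4]6 by 0.25 ± 0.07 (adjusted p = 0.0037 over the 3 strategies, 0.9999 over all genes by edgeR), and not in 6[4]10 or 2+6[8]10 (adjusted p = 0.83 and 0.19 over the 3 strategies). Between NTC and untreated animals Htt did not pass in any genotype or strategy, and the largest difference was 0.10 ± 0.08, in zQ175 in 6[4]10. Without treatment, Htt was 18.6%, 23.0% and 18.7% lower in zQ175 than in wild type (log2 fold changes of -0.30 ± 0.05, -0.38 ± 0.08 and -0.30 ± 0.06, adjusted p = 6.0e-06, 3.7e-04 and 4.8e-05).

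**Figure D2:**
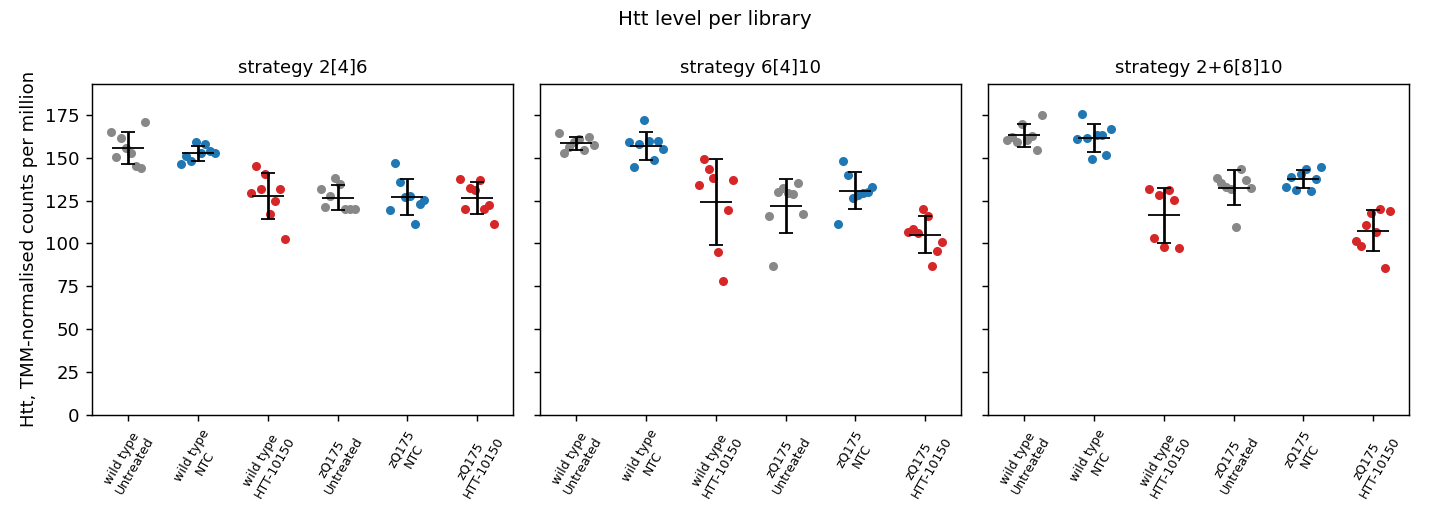
Htt in each library (y axis, TMM-scaled CPM) by genotype and treatment (x axis, colours) for the 3 strategies; each point is 1 animal, and bars are the mean and SD of 8 animals (7 for wild type with HTT-10150 in 2+6[8]10). The group means with HTT-10150 lie below those with NTC except in zQ175 in 2[4]6, where they are 126.5 and 127.1.

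Whether HTT-10150 moved the striatum of zQ175 towards wild type was asked with the genotype signature score, which is high where genes raised in untreated zQ175 are high and genes lowered there are low. The treated zQ175 animals covered 3.90% of the distance between zQ175 and wild type given NTC in 2+6[8]10 (95% interval -0.65% to 8.04%, exact permutation p = 0.13), -7.03% in 2[4]6 (-13.0% to -0.68%, exact p = 0.053) and -5.27% in 6[4]10 (-20.7% to 5.47%, exact p = 0.65). None passed when adjusted over the 3 strategies (exact p = 0.19, 0.16 and 0.65). The highest upper end of the 3 intervals was 8.04%. The negative sign in 2[4]6 rests on the NTC animals, whose mean score in zQ175 was -0.587, against -0.546 with HTT-10150 and -0.540 without treatment; the untreated animals chose the genes of the score, so they give no test of that NTC level. Between zQ175 and wild type given NTC the score differed by 0.59, 0.57 and 0.65 in 2[4]6, 6[4]10 and 2+6[8]10 (exact p = 1.6e-04 in each, the smallest possible). Single striatal genes showed the same small sizes: with HTT-10150 in zQ175 in 2+6[8]10, Penk was at 0.08 ± 0.05, Adora2a at 0.11 ± 0.05, Drd1 at 0.01 ± 0.05, Drd2 at 0.02 ± 0.05 and Pde10a at -0.10 ± 0.06 on the log2 scale (adjusted p = 0.38, 0.23, 0.93, 0.87 and 0.34). In 6[4]10 the value was 2.996% without the animals numbered male replicate 2. Scored with the signature of 6[4]10 it was -0.34% in 2+6[8]10.

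**Figure D3:**
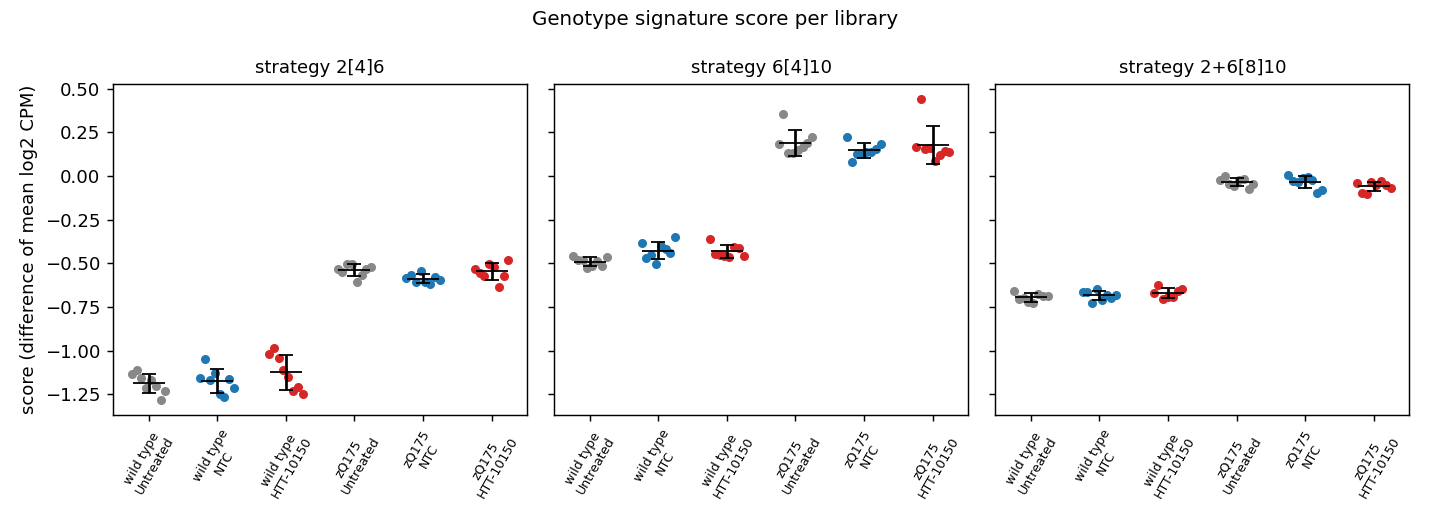
Genotype signature score of each library (y axis, mean log2 CPM of genes higher in untreated zQ175 minus that of genes lower) by genotype and treatment (x axis, colours) for the 3 strategies; each point is 1 animal and bars are the mean and SD. The untreated animals chose the genes of the score, and NTC and HTT-10150 groups of 1 genotype differ by less than 0.05 in each strategy.

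In 2+6[8]10, 490 genes were called in zQ175 with HTT-10150 against NTC, 170 up and 320 down, and the genes that fell were long. Among the largest decreases were Grin2a (ENSMUSG00000059003, chromosome 16, 9567898 to 9995560), an NMDA receptor subunit gene, at 17.6 ± 2.19 against 26.9 ± 2.02 (log2 -0.61 ± 0.10, adjusted p = 4.4e-04), the kinase gene Dgkh (-0.61 ± 0.11), Ptar1 (-0.54 ± 0.12), Syt14 (-0.52 ± 0.12) and Gprin3 (-0.51 ± 0.11). Among the largest increases were the long noncoding RNAs Gm14827 (ENSMUSG00000084904, chromosome X, 94442732 to 94447727; 0.73 ± 0.12, adjusted p = 4.4e-04) and Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672), which stood at 1332 ± 155.5 against 921 ± 125 (0.53 ± 0.11, adjusted p = 0.0059). Muc3a rose by 0.77 ± 0.18, Fxyd3 by 0.92 ± 0.24 and Syne4 by 0.69 ± 0.16. Prox2os, an RNA antisense to another gene, rose by 0.73 ± 0.16, and its reads could be split with that gene. Gm13341 was also called (0.87 ± 0.25), with a level of 6.86 ± 7.23 that varied between treated animals by more than its mean. The median transcript length was 7233 bases for the genes that fell, 1997 for those that rose and 3366 for all genes tested. Their median GC content was 45.6%, 52.5% and 49.7% in the same order. Across genes, which are not independent replicates, the fold change fell with length (Spearman's rho -0.385, Pearson's r -0.267), and the slope of gene level on length differed between the groups (-0.023 ± 0.021 against 0.014 ± 0.016, n = 8 each, exact permutation p = 0.0023, adjusted p = 0.035 over 15 comparisons). Correlations across genes of the opposite sign, with slopes that did not pass, were seen for HTT-10150 in zQ175 in 2[4]6 (rho 0.234, exact p of the slopes 0.044, adjusted p = 0.24) and for NTC against untreated zQ175 animals in 6[4]10 (rho 0.265, adjusted p = 0.70), and in wild type in 2+6[8]10 rho was -0.0239. With each library's length and GC slopes as covariates, edgeR called 2 genes, 1 of them (Gm14827) among the 490, with 1516 at an unadjusted p under 0.05. The median fold change of the 489 called genes other than Htt then went from 0.163 (interquartile range 0.132 to 0.252) to 0.0852 (0.0542 to 0.162) on the log2 scale. The median standard errors were 0.0421 and 0.0430, the second worked back from the p values.

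**Figure D4:**
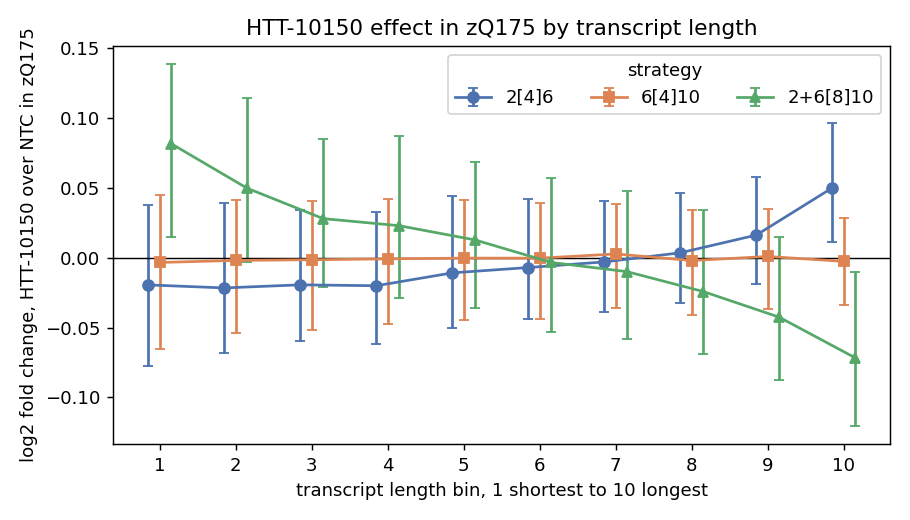
Log2 fold change with HTT-10150 against NTC in zQ175 (y axis) by bin of transcript length (x axis, from the shortest to the longest) for the 3 strategies; points are medians over the genes of a bin and bars the interquartile range. In 2+6[8]10 the median goes from 0.08 in the shortest bin to -0.07 in the longest.

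By group, the calls in zQ175 in 2+6[8]10 were spread thinly over the fixed lists. Of 23 clustered protocadherins, 1 fell and 0 rose (2 down adjusted over the list alone), which was Pcdhb2 (-0.43 ± 0.12), a gene that was higher in untreated zQ175 than in wild type (0.999 ± 0.13). Of 24 cholesterol synthesis genes 1 rose, Msmo1 (0.17 ± 0.05), and of 29 respiratory chain genes 1 rose, Ndufb3 (0.13 ± 0.04), with 1 and 9 up adjusted over the list alone. These 3 lists passed camera (adjusted p = 0.0010, 0.0042 and 0.0022), but not with an estimated correlation (adjusted p = 0.99 for each). The list tests took no account of the trend with transcript length in this comparison. Of the 33 medium spiny neuron genes 1 fell and 0 rose, of 10 direct and 9 indirect pathway markers 0 changed, and of 16 astrocyte and 16 oligodendrocyte markers 0 changed. Of the 489 called genes other than Htt, 192 were also genotype genes; 116 moved against the genotype effect and 76 with it. The share against it was 60.4%, where the median of 10000 draws of genotype genes, matched on the direction of the treatment change, was 54.7% and a share of 0.0558 of the draws reached as much. DESeq2 called 808 genes and the fit of all 143 libraries 173, and without the animals numbered female replicate 1 the count was 197, without a filter on low counts 292 and against untreated animals 191. Beside these calls, lists that mark neighbouring tissue did not pass camera (choroid plexus median 0.17, cortical 0.10, thalamic -0.08, adjusted p = 0.85, 0.53 and 0.69).

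After treatment at a single age, HTT-10150 left 0 genes called by edgeR in zQ175, with 821 genes at an unadjusted p under 0.05 in 2[4]6 and 561 in 6[4]10, and 0 called by DESeq2 in each. The genes named in advance had small fold changes: in 2[4]6 Penk was at -0.10 ± 0.07, Drd1 at -0.07 ± 0.07 and Adora2a at -0.07 ± 0.08, and in 6[4]10 they were at -0.04 ± 0.08, -0.04 ± 0.09 and -0.04 ± 0.12. Choroid plexus and ependymal markers, which come from tissue next to the striatum, had a median log2 fold change of -1.55 in 6[4]10, with 8 of 12 down adjusted over the list alone, and passed camera (adjusted p = 8.3e-10), but not with an estimated correlation (adjusted p = 0.26). None passed over all genes, and the levels of Folr1, Kcnj13 and Aqp1, among the largest decreases, varied between NTC animals by more than their mean (Folr1 at 0.69 ± 0.36 against 6.60 ± 12.7 with NTC, adjusted p = 0.60). The list was higher with NTC than without treatment in the same strategy (median 1.204, 0 called, 7 up adjusted over the list alone; camera adjusted p = 0.0012, and 0.73 with an estimated correlation). In 2[4]6 camera passed 8 of 26 lists, among them interferon response genes (median -0.17) and medium spiny neuron identity (-0.06), and 0 with an estimated correlation (adjusted p = 0.63 and 0.64). The effect in 2+6[8]10 differed from that in 6[4]10 for Gm14827 (0.92 ± 0.18), Muc3a (1.002 ± 0.21) and Xpr1 (-0.24 ± 0.05). Against 2[4]6 it differed for 5 genes, of which Acta2, Tagln and Myl9, genes of smooth muscle, were higher (0.92 ± 0.16, 0.81 ± 0.17 and 0.54 ± 0.12) and Dgkh and Arfgef3 lower (-0.94 ± 0.19 and -0.63 ± 0.14). Between 6[4]10 and 2[4]6 edgeR called 0, with 814 at an unadjusted p under 0.05; DESeq2 called 49, 57 and 0 in these comparisons. Females and males did not differ in this effect for any gene with edgeR or DESeq2 in any strategy, with 5.52%, 3.50% and 3.16% of genes at an unadjusted p under 0.05 in 2[4]6, 6[4]10 and 2+6[8]10.

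In wild-type mice, HTT-10150 changed few genes other than Htt against NTC. In 2+6[8]10, Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), a microglial receptor gene, stood at 22.7 ± 3.94 (n = 7) against 17.2 ± 2.84 (n = 8), a rise of 0.48 ± 0.07 (adjusted p = 6.2e-05), and Htt fell. Microglia markers were higher as a group: 1 of 18 rose and 0 fell, 11 rose adjusted over the list alone, and 17 of 18 had a positive fold change, such as C1qa (0.22 ± 0.06) and Itgam (0.20 ± 0.05). The median was 0.13, and the list passed camera (adjusted p = 2.2e-17), also with an estimated correlation (adjusted p = 0.010). NTC animals had lower values of this list than untreated ones (median -0.04, with Fcrls and Itgam called), a difference that passed camera but not with an estimated correlation (adjusted p = 0.81). Against untreated animals, Fcrls did not pass (adjusted p = 0.9997) and the list's median was 0.09. In 2[4]6 edgeR called Abca8a, a lipid transporter gene (0.32 ± 0.06, adjusted p = 0.020), and DESeq2 called 2; without a sex term its adjusted p was 0.055. In 6[4]10 edgeR and DESeq2 called 0 genes, with 517 at an unadjusted p under 0.05. In 2[4]6, camera passed 15 of 26 lists, among them medium spiny neuron identity (median -0.10) and oligodendrocyte markers (0.09), and 0 with an estimated correlation (adjusted p = 0.37 for both).

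The effect of HTT-10150 differed between zQ175 and wild type for 82 genes in 2+6[8]10, with 36 higher and 46 lower in zQ175 relative to wild type. Muc3a (1.203 ± 0.26), Gm14827 (0.97 ± 0.18), Malat1 (0.76 ± 0.16) and the thrombospondin gene Thbs3 (0.74 ± 0.14) had higher effects in zQ175. Klf12 (-0.82 ± 0.13, adjusted p = 0.0019), Ptar1 (-0.76 ± 0.17), Parp14 (-0.72 ± 0.16), Aff2 (-0.67 ± 0.15), Dgkh (-0.65 ± 0.16) and Xkr4 (-0.64 ± 0.14) had lower ones. Microglia markers (0 called, 5 of 18 lower adjusted over the list alone, median -0.12) and interferon response genes (Parp14 the only call, median -0.28) passed camera, but not with an estimated correlation (adjusted p = 0.68 for both). Camera also passed thalamic and septal markers, clustered protocadherins and respiratory chain genes. That made 5 of 26 lists, and 0 with an estimated correlation. DESeq2 called 220 genes, while the count was 3 without the animals numbered female replicate 1, 0 with the number in the library name as a block, and 5 with the length and GC slopes as covariates. With those slopes the 82 genes kept 70.8% of their median fold change (0.3885 to 0.2751 on the log2 scale), and 82 kept their sign. In 2[4]6 and 6[4]10 edgeR and DESeq2 called 0, with 398 and 673 genes at an unadjusted p under 0.05.

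NTC was compared with no treatment to measure what the control itself changed. In wild type in 2+6[8]10 it changed 28 genes, 11 up and 17 down. Dcn, an extracellular matrix gene, fell by 0.67 ± 0.14 on the log2 scale, Ptgds, a prostaglandin synthase gene, by 0.44 ± 0.10, and the microglial genes Fcrls and Itgam by 0.36 ± 0.07 and 0.24 ± 0.05, while Aldh1l2, Traip and Ttc13 rose by 0.45 ± 0.09, 0.42 ± 0.09 and 0.25 ± 0.05. Thalamic and septal markers had a median of -0.19, with 0 of 10 called and 3 down adjusted over the list alone, and passed camera, but not with an estimated correlation (adjusted p = 0.18). With the 4 tissue marker levels as covariates 7 genes were called, where the 28 kept 81.4% of their median fold change (0.303 to 0.247) and the same signs, with the number in the library name as a block 2, and without the animals numbered male replicate 2 the count was 5; DESeq2 called 79. In the other comparisons of NTC with no treatment edgeR and DESeq2 called 0, with 316 and 394 genes at an unadjusted p under 0.05 in wild type in 2[4]6 and 6[4]10, and 785, 1167 and 473 in zQ175 in 2[4]6, 6[4]10 and 2+6[8]10. In 6[4]10, interferon response genes had a median of -0.27 in wild type (3 of 23 down adjusted over the list alone) and endothelial and mural markers one of -0.13, and both lists passed with an estimated correlation (adjusted p = 0.040 and 0.031). With fry, 0 of 26 lists passed there. The interferon genes that the rule names fell more in females, such as Irf9 (-0.51 against -0.0097 in males), a difference that was not tested. Oasl2 varied more between untreated animals (4.97 ± 2.31) than with NTC (2.81 ± 0.71).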

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

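Of the tests below, those with length and GC slopes or tissue markers as covariates, the test of a return towards wild type and the test of the NTC level were chosen only after the result was seen, and the bound that would exclude a return towards wild type was reworded 2 times after its values were known, where both earlier wordings would have excluded it.

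Each of the 18 groups was tested on 3 measures (Htt level, signature score and total count). Of these 54 tests, 7 found 1 library far from the others, where chance gives about 1 in 20. Htt stood at 109.6 in untreated zQ175 male replicate 3 of 2+6[8]10 (others 131.8 to 143.2) and at 86.99 in untreated zQ175 male replicate 2 of 6[4]10 (others 115.9 to 135.2). The signature score was 0.44 in zQ175 HTT-10150 male replicate 2 of 6[4]10 (others 0.09 to 0.16) and 0.36 in untreated zQ175 male replicate 2 of 6[4]10 (others 0.13 to 0.23). Total counts were 20.77 M in untreated wild-type female replicate 4 of 2+6[8]10 (others 13.45 M to 15.2 M), 29.19 M in untreated wild-type female replicate 4 of 2[4]6 (others 16.55 M to 22.13 M) and 27.81 M in untreated wild-type male replicate 1 of 6[4]10 (others 16.92 M to 18.8 M).

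Effects differed between groups in the following tests. The HTT-10150 effect on Htt differed between genotypes in 2[4]6 by 0.25 on the log2 scale, and 82 genes differed between genotypes in 2+6[8]10. Between strategies, the effect of HTT-10150 in zQ175 differed for 3 genes (2+6[8]10 against 6[4]10) and 5 genes (2+6[8]10 against 2[4]6), and the genotype effect for 2 genes (2+6[8]10 against 6[4]10), 11 genes (2+6[8]10 against 2[4]6) and 136 genes (6[4]10 against 2[4]6). In data that no comparison uses, the entry for a mutant form of Htt had 1 or more counts in 64 of 72 zQ175 libraries and in 0 of 71 wild-type libraries. Its level, with group means of at most 0.153 CPM, is too low to measure whether HTT-10150 lowered this form (0.1004 against 0.142, 0.0883 against 0.0769 and 0.0987 against 0.153 with NTC, exact permutation p = 0.23, 0.73 and 0.11).

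The 490 genes called with HTT-10150 in zQ175 in 2+6[8]10 were weighed against 3 explanations. With tissue markers as covariates, 95.4% of the median fold change of the called genes was kept. This argues against a shift in the share of choroid plexus, cortical, thalamic or oligodendrocyte tissue. Other cell types, such as those of vessels, were not covariates, so their share was not tested. With length and GC slopes as covariates 52.3% was kept, between the bounds set for and against. The fold changes shrank (median 0.163 to 0.0852), with a median standard error of 0.0421 before and 0.0430 after. The second was worked back from the p values, so the 2 compare only roughly. A trend with gene length between the libraries and an effect of treatment on long genes cannot be told apart here, since the slopes themselves differ between the groups. A share of 0.0558 of draws had as many genes moving against the genotype effect, and whether part of the change is a return towards wild type stays open.

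Htt was lower with HTT-10150 in wild type and not in zQ175 in 2[4]6. An exchange of HTT-10150 and NTC labels in zQ175 would leave lowered libraries among the 16, and 3 of them (1 HTT-10150 and 2 NTC) lay below the lowest untreated one, fewer than the 4 set as the bound. The NTC and untreated levels differed by at most 11.2% of the difference of effects, which argues against a shifted NTC group. A difference between genotypes in the response, animals that did not receive the compound, and labels exchanged with samples outside these groups were not tested and stay open.

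Microglia markers were higher with HTT-10150 in wild type in 2+6[8]10. If low levels in the NTC libraries were the source, the rise would shrink against untreated animals, and 70.3% of the median was kept (0.13 against NTC, 0.09 against untreated), between the bounds set for and against. Low NTC levels as part of the pattern and an effect of treatment cannot be told apart with this value. The median of NTC against untreated animals was -0.04, with 13 of 18 members lower.

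Other splits of the same animals were fitted to see how often they give as many calls. For the genotype effect, 1 of 40 splits, the real one, reached the count in each strategy (5122, 5691 and 5483, with 0, 3581 and 984 as the highest others). The same held in 2+6[8]10 for HTT-10150 in zQ175 (490, highest other 3), the difference between genotypes (82, highest other 1) and NTC in wild type (28, highest other 2). Here 1 of 40 is the fewest possible and was not adjusted over the tests, and the splits ignored the number in the library name. With that number as a block the counts were 562, 0 and 2, so the last 2 results rest on leaving it out. For HTT-10150 in wild type, 3 of 40 splits gave as many in 2[4]6 (1, highest other 5) and in 2+6[8]10 (2, highest other 4), so chance is not excluded. Where 0 genes were called, any split gives as many whatever the data, so the 40 splits test nothing there. The highest others in 2[4]6 were 9 for HTT-10150 in zQ175, 0 for the difference between genotypes, and 2 and 1 for NTC in zQ175 and wild type. In 6[4]10 they were 1 and 1 for HTT-10150 in zQ175 and wild type, 11 for the difference between genotypes, and 118 and 1 for NTC in zQ175 and wild type. In 2+6[8]10 the highest other was 1 for NTC in zQ175. Differences between sexes were 0 in each case, which any of the 30 splits reaches, so they give no test. The highest others were 0, 0 and 1 for the genotype effect and 50, 1 and 0 for HTT-10150 in zQ175 in 2[4]6, 6[4]10 and 2+6[8]10. For differences between strategies in the HTT-10150 effect, 2 of 21 splits gave as many for 2+6[8]10 against 6[4]10 (3, highest other 101) and 3 of 21 for 2+6[8]10 against 2[4]6 (5, highest other 72), and chance is not excluded. For 6[4]10 against 2[4]6 the count was 0 (highest other 1), which any split reaches. For the genotype effect, 2 of 21 splits gave as many for 2+6[8]10 against 6[4]10 (2, highest other 7), where chance is not excluded. The real split alone reached the count for 2+6[8]10 against 2[4]6 (11, highest other 2) and for 6[4]10 against 2[4]6 (136, highest other 43). That is 1 of 21, the fewest possible, and it was not adjusted over the tests, so chance is not firmly excluded there. The splits with 118, 101, 72 and 50 calls, where the real counts were 0, 3, 5 and 0 and the median of the other splits was 0, point to a structure of the samples in single splits, which was not tested.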

How the results depend on the processing

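The tests with length and GC slopes or tissue markers as covariates, and those without the libraries that stand apart by choroid plexus or cortical genes, were chosen only after the results were seen. The genotype counts stayed within 1.5 times their value in every alternative run for them, which leaves out the name number block, including leaving out each replicate number (4382 to 4971, 4965 to 5301 and 4885 to 5511 in 2[4]6, 6[4]10 and 2+6[8]10). HTT-10150 in zQ175 called 1 gene in 2[4]6 with the replicate block and 2 against untreated animals. In 2+6[8]10 it called 808 with DESeq2, 292 with no filter, 2 with length and GC covariates, 296 without the libraries that stand apart, 191 against untreated animals, and 197 (without female replicate 1) to 506 without each replicate. In wild type in 2[4]6 it called 2 with DESeq2, each block and length and GC covariates, 0 with only the groups compared, no sex term or tissue covariates, and 0 to 2 without each replicate. The wild-type count in 2+6[8]10 was 6 with DESeq2, 5 with only the groups compared, 1 with no sex term or against untreated animals, 7 with tissue covariates, 4 without the libraries that stand apart and 2 to 7 without each replicate. NTC in wild type called 1 gene in 2[4]6 with length and GC covariates (0 to 1 without each replicate), and in 2+6[8]10 79 with DESeq2, 63 with only the groups compared, 2 with the name number block, 46 with length and GC covariates, 7 with tissue covariates and 5 (without male replicate 2) to 30 without each replicate. NTC in zQ175 called 2 in 2+6[8]10 with tissue covariates. The difference between genotypes in 2+6[8]10 had 220 genes with DESeq2, 27 with no filter, 54 with no sex term, 44 with the replicate block, 0 with the name number block, 5 with length and GC covariates, 33 without the libraries that stand apart, and 3 (without female replicate 1) to 117 without each replicate. DESeq2 called 49 and 57 genes for the strategy differences of HTT-10150, 27 and 294 for those of the genotype effect, and 22 for the sex difference of the genotype effect in 6[4]10. The cause was not tested.

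Htt in wild type in 2[4]6 passed with DESeq2 (-0.25), the replicate block (-0.26), the name number block (-0.27), length and GC covariates (-0.28) and untreated animals (-0.28), and ran from -0.29 to -0.21 without each replicate (adjusted p = 0.023 to 0.70). In zQ175 in 2+6[8]10 it did not pass with length and GC covariates (-0.26, adjusted p = 0.10), and ran from -0.39 to -0.32 without each replicate. The other ranges of Htt without each replicate were -0.04 to 0.04 and -0.35 to -0.28 for HTT-10150 in zQ175 in 2[4]6 and 6[4]10, -0.40 to -0.26 and -0.54 to -0.45 in wild type in 6[4]10 and 2+6[8]10, and 0.21 to 0.30, -0.04 to 0.08 and 0.09 to 0.19 for the difference between genotypes. For zQ175 against wild type they were -0.32 to -0.26, -0.40 to -0.32 and -0.31 to -0.27, for NTC in zQ175 -0.04 to 0.02, 0.02 to 0.13 and 0.0087 to 0.08, and for NTC in wild type -0.06 to -0.0065, -0.03 to -0.0025 and -0.03 to 0.0008. The percent of the signature returned was 0.876 and 2.20 against untreated animals in 2[4]6 and 6[4]10, a reference that also chose the signature genes, and -0.34 with the signature of 6[4]10 in 2+6[8]10; without each replicate it ran from -8.51 to -5.16, -7.75 to 2.996 (without male replicate 2) and 2.79 to 5.40. With an estimated correlation camera called 5, 4 and 5 lists for the genotype effect, and fry 15 in 2[4]6. For HTT-10150 in wild type each called 1 in 2+6[8]10 and 0 elsewhere, for NTC in wild type camera called 2 in 6[4]10 and fry 1 in 2+6[8]10, and for HTT-10150 in zQ175, the difference between genotypes and NTC in zQ175 each called 0. With NTC animals for the genotype effect 8 named genes changed sign: Bst2 (0.245), Ifitm3 (0.088), Rsad2 (0.26), Uqcrh (-0.00779) and Uqcrc2 (-0.0031) in 2[4]6, Rsad2 (0.22) and Ndufb5 (-0.0067) in 6[4]10 and Cp (0.055) in 2+6[8]10. The cause was not tested. Of 362 named gene results, 347 kept direction and side of the threshold with DESeq2, 361 with RLE size factors, 332 with no filter, 342 with no sex term and 307 with length and GC covariates. With the name number block it was 19 of the 54 treatment results, and against untreated animals 10 of 21. With NTC animals 261 of the genotype results were kept, 39 did not pass and 8 changed sign, as above. As a check of pairing, residual correlations between animals of the same replicate number ran from -0.244 to 0.359 in 118 pairs over 15 comparisons. Of these, 39 were over 0.1, and 45 correlated best with their own number. No rate expected by chance was set beside these counts, so the check does not exclude pairing. It used the replicate number and not the number in the library name. The replicate block was kept as an alternative alone.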

Other observations

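No test in this part was chosen after a result was seen. The lists not described above showed mixed changes between untreated zQ175 and wild type, and none passed camera. Of 24 cholesterol synthesis genes, 3, 4 and 2 rose and 6, 9 and 7 fell in 2[4]6, 6[4]10 and 2+6[8]10, with Insig1 at -0.40, -0.50 and -0.42 and Msmo1 at -0.33, -0.37 and -0.39 on the log2 scale. Of 16 p53 target genes, 2, 2 and 3 rose and 4, 4 and 3 fell, and Cdkn1a, a cell cycle inhibitor gene, was at -0.81, -0.78 and -0.69. Of 16 genes of the unfolded protein response, 0, 2 and 2 rose and 4, 1 and 3 fell, with Trib3 at -1.01, -0.89 and -0.86. Of 17 heat shock genes, 3, 3 and 2 rose and 1, 0 and 1 fell, with Hspa8 at 0.18, 0.33 and 0.30. Of 13 genes of the small RNA machinery, 6, 1 and 1 rose and 2, 3 and 2 fell, with Ago4 at -0.63, -0.82 and -0.70 and Prkra at 0.46, 0.28 and 0.31. Of 13 reactive astrocyte genes, 1, 2 and 3 rose and 1 fell in each strategy, with Serpina3n at 0.40, 1.003 and 0.79. Of 11 oligodendrocyte precursor markers, 1, 2 and 2 rose and 1 fell in each, with Enpp6 at 0.58, 0.48 and 0.53. Of 18 microglia markers, 1, 0 and 1 rose and 5, 3 and 2 fell.

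Some markers of neighbouring tissue were called between genotypes, and cortical ones in 2+6[8]10 had the largest count of a list in 1 strategy. Of 12 cortical markers 1, 1 and 1 rose and 1, 2 and 4 fell, of 10 thalamic and septal markers 2, 1 and 0 rose and 0, 0 and 1 fell, and of 12 choroid plexus and ependymal markers 1, 1 and 0 rose and 0 fell. The median and mean differed in sign from the direction of camera for cortical markers in 6[4]10 (median 0.41) and 2+6[8]10 (0.14), choroid plexus markers in 2[4]6 (-0.38), p53 target genes in 6[4]10 (0.05), heat shock genes in 2[4]6 (-0.03) and 2+6[8]10 (-0.06) and the unfolded protein response in 6[4]10 (-0.03). The median alone differed in sign from the mean for oligodendrocyte precursor markers in 2[4]6 and 6[4]10 (-0.01 and -0.03), and for the small RNA machinery (0.01) and the respiratory chain (0.02) in 2+6[8]10.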
